A study of Zea mays with 4 samples.

How the data were processed

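RNA from the elongation zone of the sixth leaf of the maize inbred line B73, grown in hydroculture, was sequenced in 4 libraries. Both HN libraries came from plants supplied with 4 mM nitrogen and both LN libraries from plants supplied with 0.04 mM nitrogen. The source label of the HN samples writes the dose with the unit nM, while their description gives mM, and the mM value was used. Nothing in the labels says that the libraries of a group came from separate plants or cultures, so p-values measure only the spread between these samples, which may be technical.

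The deposited table held FPKM values (fragment numbers scaled by transcript length and by the mapped fragments of the library) for each library, together with the authors' own comparison of LN with HN. The authors' log2 fold change, p-value and q-value stood in columns of that table, per the file headers. The submitters' processing notes name TopHat2, edgeR and the genome build B73 RefGen_v3, without versions. The transcript assembler was not given in the sources used here. The deposited q-values differed from a Benjamini-Hochberg adjustment of the deposited p-values by at most 1.22e-06. The authors' log2 fold change lay -0.0967 from the log2 ratio of mean FPKM at the median of 14995 loci, and 90.5% of these loci were within 0.1 of that median. Both HN columns carried 1 and the same name, so they were assigned to the HN group without a replicate number. HN1 denotes the first and HN2 the second of these columns, and these names pair nothing with LN1 or LN2.

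The table had 31324 rows for 30378 loci. Another 946 rows repeated a locus under a second gene name with identical FPKM values, and 851 loci held several genes. These shared loci were tested once and kept out of the gene lists and the named genes. Of the loci, 3431 carried no gene model name. Among 27390 other gene names, 16780 matched 1 gene of the reference gene table (assembly Zm-B73-REFERENCE-NAM-5.0, used for names alone), 470 matched several and 10140 matched none. A symbol was found for 2292 gene names. Coordinates are those of the deposited loci, and whether a position is exonic or intronic was not analysed here.

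No read counts were used, because the values are FPKM, and absolute depth is unknown. Relative depth was estimated from the lowest FPKM values, where a locus holds few reads. With LN1 set to 100%, LN2 had 91.6%, HN1 75.8% and HN2 64.4%, so the HN libraries were the shallower ones.

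The main test was limma-trend on log2(FPKM + 1), with loci kept at 1 FPKM or more in at least 2 libraries, group as the only term and Benjamini-Hochberg adjustment at a threshold of 0.05. The design had been written for either counts or normalized values, and the branch for normalized values applied. Fold changes are on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes. Errors in parentheses after FPKM values are SDs over n = 2 libraries. limma's residual degrees of freedom were 2 and its prior degrees of freedom 3.48. On simulated data for LN against HN (22489 loci, 20 runs), 0.4% of changes of log2 size 1, 36% of size 2 and 91.4% of size 4 were called, none with the wrong sign, and 5.1% of all calls were false. The simulated loci varied independently and with the same spread in both groups. In the data the HN pair differed more than the LN pair, so these shares need not hold there.

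Before the data were examined, 31 gene lists were fixed as search patterns for symbols and descriptions. The reference gene table held no descriptions, so 5 of these lists reached the minimum of 3 tested members and 26 did not, of which 20 had no tested member. A further 33 lists were therefore written on symbols and synonyms after the table's format had been seen. The total counts of called loci and a few rows, CAB1 among them, had been looked at by then, but no list or named-gene result. Of these symbol lists 29 had at least 3 tested members. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of each kind, and again with camera at an estimated correlation and with fry. With an estimated correlation, camera refers its statistic to the 2 residual degrees of freedom. It therefore had little power here, whatever the correlation. On simulated data for LN against HN (22489 loci), camera called the shifted list in 20 of 20 runs and no other list. The simulated genes varied independently, so these runs cannot show how often camera calls lists of correlated genes wrongly.

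Named genes followed a rule fixed before the data were examined. It took the 8 largest rises and 8 largest falls past the threshold with a symbol, a mean of at least 5 FPKM and no overlap between the groups. It added up to 4 members of each list past the threshold by smallest adjusted p, or the 2 with the highest mean level where none passed. It also took the tested gibberellin biosynthesis genes and the nitrogen assimilation genes past the threshold. Members of the symbol lists were taken by the same rule, and some beyond the first 2 of a list are left out. Some symbols are carried by more than 1 locus. Another tested locus with the symbol of CER1, kin1, pep1, GLN2, RPL10, AUX1, pac1 or Agp2, and the other loci named Laccase-13, did not pass the threshold, so values belong to the positions given. Members of multigene families, such as the histone, light-harvesting, rubisco small subunit and ribosomal protein genes, share near-identical sequence, so their separate levels are uncertain.

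Alternatives chosen before the data were examined were a pseudocount of 0.1, a filter at any value above 0 or at 5 FPKM, stricter thresholds, each library left out in turn, an estimated correlation and fry. Alternatives chosen after seeing the data were a pseudocount of 0.5, median-of-ratios scaling, quantile normalization, removal of loci listed at 0 in one library, single-gene annotated loci, array weights, removal of a trend on locus span, and the authors' q-values. Count-based alternatives were not run because the values are FPKM. Tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.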

Results

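Transcript levels were measured by RNA sequencing in the elongation zone of maize leaf 6, the part of the growing blade where cells lengthen after they have left the division zone. B73 is the inbred line of the maize reference genome. The design set 2 libraries from low-nitrogen plants (LN, 0.04 mM) against 2 from plants with control nitrogen (HN, 4 mM). The series' title names leaf cell flux, cell elongation and gibberellin synthesis as its subject. FPKM totals were 814307 in HN1, 1113330 in HN2, 666397 in LN1 and 710263 in LN2.

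Genes of cytosolic ribosomal proteins, DNA replication, photosynthesis and benzoxazinoid defence were lower in LN than in HN, by camera tests of gene lists given with each group. Lists for cellulose deposition, auxin, and autophagy and senescence proteases were higher by the same tests. None of these list calls, lower or higher, held with an estimated correlation, where camera has only 2 residual degrees of freedom. The lipoxygenase gene lox1 fell from 346 ± 30.4 FPKM in HN to 15.3 ± 5.09 in LN (SD, n = 2). The wax gene CER1 rose from 2.27 ± 0.312 to 16.1 ± 1.63 FPKM. limma called 1121 of 22489 tested loci, 266 higher and 855 lower in LN, so 76.3% of the calls were lower. Of these calls, 1052 were also called in the same direction in the authors' deposited table, which called 4359 of the tested loci. Under quantile normalization, an alternative chosen after seeing the data, the lower share was 64.3%. The count rose without either HN library, where the spread was estimated from the LN pair alone. It fell without either LN library, where the spread came from the HN pair, which differed more. The lower share was smaller in each of these fits. With a pseudocount of 0.1 in place of 1 the calls fell to 32 higher and 69 lower, and with all loci above 0 tested to 1, so 12 and 0 of the 48 genes named as changed were still called.

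The 8 largest falls were spread over several functions. lox1 (chromosome 3, 168738872 to 168882335, B73 RefGen_v3 as are all positions here) fell by 4.45 on the log2 scale (SE 0.29, limma adjusted p = 0.0202). Its locus spans 143464 bp, the longest of the jasmonate list (median 3271 bp), so the level may not be that of lox1 alone. D14a, related to the strigolactone receptor D14 (chromosome 1, 22436997 to 22439491), fell from 40.0 ± 4.32 to 1.45 ± 0.177 FPKM (adjusted p = 0.0127). The polyamine oxidase gene MPAO (chromosome 10, 62260919 to 62265303) fell from 1076 ± 440 to 86.5 ± 6.48 FPKM. kin1 (chromosome 7, 176260710 to 176262411) fell from 34.2 ± 14.6 to 2.28 ± 0.729 FPKM. GLK44, a member of the G2-like transcription factor family (chromosome 1, 280284827 to 280286869), fell from 11.9 ± 2.34 to 0.343 ± 0.0327 FPKM. CYP71C4, the cytochrome P450 also known as BX2 (chromosome 4, 3265212 to 3267368), fell from 137 ± 20.3 to 14.3 ± 3.70 FPKM. pep1, the phosphoenolpyruvate carboxylase gene (chromosome 9, 62306265 to 62311673), fell from 53.1 ± 3.60 to 6.18 ± 0.454 FPKM. The chlorophyll-binding protein gene cab-m1 (chromosome 8, 141176050 to 141177936) fell from 677 ± 173 to 111 ± 66.0 FPKM. Adjusted p-values of the last 6 genes ranged from 0.0203 for pep1 to 0.0479 for cab-m1.

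Transcription factor genes made up 4 of the 8 largest rises. Only genes with a symbol could be chosen, and the share of transcription factors among those was not counted. NF-YA13 (chromosome 5, 211715053 to 211720050) rose from 1.63 ± 1.24 to 11.3 ± 1.34 FPKM, and NF-YA11 (chromosome 5, 16480474 to 16484941) from 2.52 ± 1.13 to 13.8 ± 0.0768 FPKM. Both encode A subunits of the CCAAT-binding nuclear factor Y. ZHD13, a zinc-finger homeodomain gene (chromosome 7, 112658776 to 112661470), rose from 4.95 ± 3.26 to 26.1 ± 4.91 FPKM. TCP30 (chromosome 3, 194948683 to 194951389) rose from 1.69 ± 1.05 to 10.8 ± 1.40 FPKM. CER1, linked to cuticular wax alkanes (chromosome 5, 29918039 to 29925862), had the largest rise, 2.39 on the log2 scale (SE 0.22, limma adjusted p = 0.0336). The protease gene see2b (chromosome 3, 225910754 to 225916465) rose from 23.9 ± 0.0157 to 116 ± 19.3 FPKM. Laccase-17 (chromosome 3, 180720547 to 180723394) rose from 2.38 ± 1.01 to 9.22 ± 1.08 FPKM. CYP714B3, a P450 of the CYP714 family (chromosome 1, 54731139 to 54737676), rose from 4.18 ± 1.02 to 14.3 ± 0.435 FPKM. The 7 rises other than CER1 had adjusted p-values from 0.0365 to 0.0473.

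**Figure D1:**
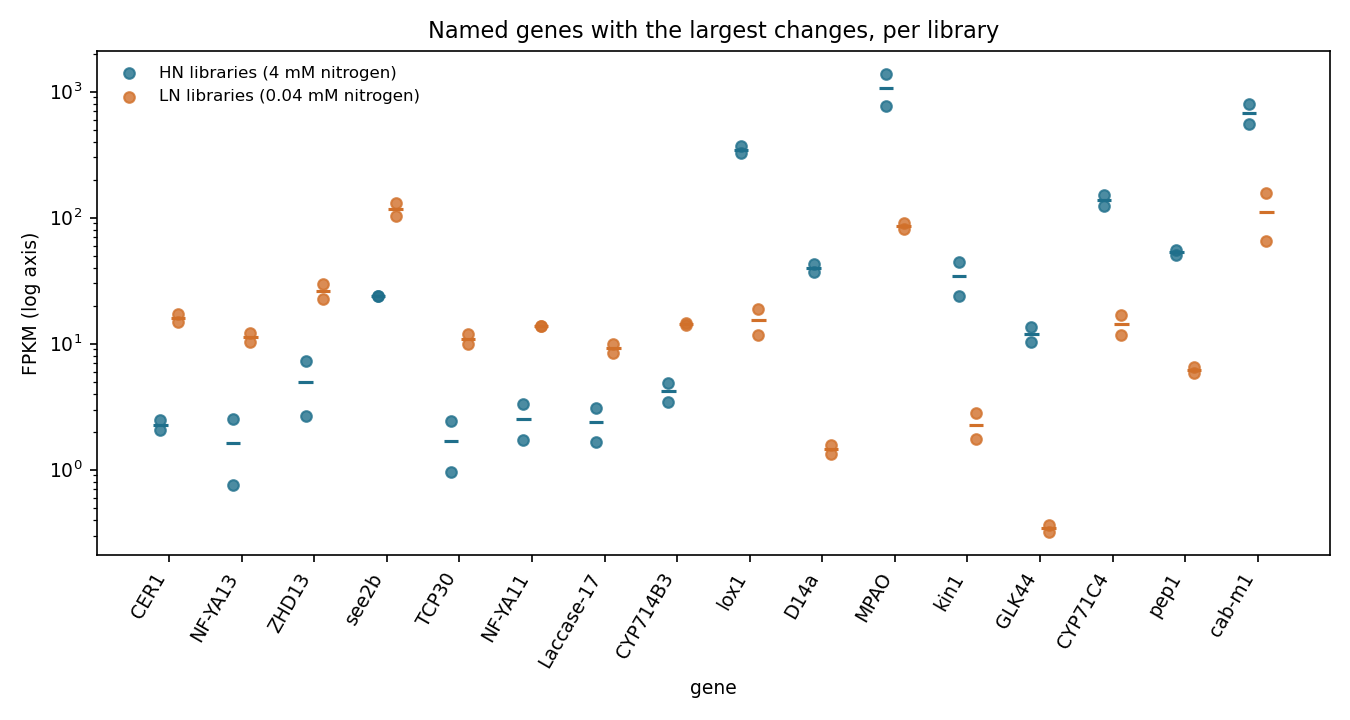
FPKM on a log axis in each library for the 8 named genes with the largest rises and the 8 with the largest falls, with 1 point per library and a bar at each group mean. Both LN libraries lie on the same side of both HN libraries for every gene plotted, by the rule that chose them.

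Of the gibberellin list, synthesis and DELLA genes matched by symbol, no tested gene passed the threshold. CYP88A1, the ent-kaurenoic acid oxidase gene known as dwarf3 (chromosome 9, 26725935 to 26729883), was at 1.76 ± 0.0799 FPKM in HN and 0.660 ± 0.109 in LN, a log2 change of -0.74 (SE 0.21, limma adjusted p = 0.0917). The DELLA repressor gene d9 (chromosome 5, 11793472 to 11795945) was at 27.5 ± 4.28 and 16.3 ± 1.36 FPKM (log2 change -0.71, limma adjusted p = 0.0959). Its relative D8 had a log2 change of -0.49 and the gibberellin 3-oxidase gene Dwarf1 one of 0.25 (limma adjusted p = 0.395 and 0.649). Dwarf1 was near the floor, at 0.897 ± 0.767 FPKM in HN. By limma 0 of the 4 passed, 2 were lower at an unadjusted p under 0.05, and the same 2, CYP88A1 and d9, had q-values of 0.0084 and 0.0416 in the authors' deposited table, with log2 fold changes of -1.53 and -0.84. Adjusted over the list alone, 2 were lower. The list's camera adjusted p was 0.193. The other listed genes, an1 and KS2.1, did not reach the filter. CYP714B3, 1 of the 8 largest rises above, was not on the list, but belongs to a P450 family that includes gibberellin oxidases in other plants. Further gibberellin genes were not analysed here.

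Cytosolic ribosomal protein genes were lower as a group. The median log2 change of 24 cytosolic ribosomal protein genes was -1.71, a 3.26-fold lower level, with all 24 negative and 7 lower past the threshold. Under quantile normalization the median was -1.02. rps24 fell from 284 ± 94.7 to 51.1 ± 9.41 FPKM and the acidic ribosomal protein gene arpp2a-2 from 110 ± 35.3 to 21.4 ± 4.55. RPL10 (chromosome 5, 19458782 to 19471472) and RP-P0 fell, with log2 changes of -2.21 and -2.08 (limma adjusted p = 0.0446 and 0.0452). Camera gave the list an adjusted p of 8.5e-12, which became 0.605 with an estimated correlation. In the authors' deposited table, all 24 had q-values under 0.05 and were lower.

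DNA replication and core histone genes were also lower. The median over 20 genes was -1.52 on the log2 scale, all 20 were negative, and 7 passed the threshold (camera adjusted p = 1.8e-08; adjusted p = 0.605 with an estimated correlation). Histone genes his2b5 and H3C2 fell from 439 ± 202 to 68.5 ± 1.16 and from 631 ± 299 to 105.4 ± 4.44 FPKM. SLD5, of the replicative helicase complex, and RNRS1, a ribonucleotide reductase small subunit, fell, with log2 changes of -1.91 and -2.21 (limma adjusted p = 0.0431 and 0.0446). Cell cycle regulators such as cyclins did not show this. Their 15 tested genes had a median log2 change of 0.05, 0 passed limma's threshold, and camera's adjusted p was 0.554. At an unadjusted p under 0.05, 4 were higher and 2 lower, and the authors' deposited table called 1 higher and 2 lower. The examples cycD2 and cyclin4 had log2 changes of -0.08 and 0.77. Another 6 cell number regulators and 15 growth-regulating factors and partners also had 0 members past limma's threshold, with 2 and 1 higher at an unadjusted p under 0.05 and 0 called in the authors' deposited table. Their medians were 0.15 and 0.31 (camera adjusted p = 0.554 and 0.128), and their most abundant members had log2 changes of -0.42 (CNR8), 0.06 (CNR6), -0.17 (GRF4) and 0.31 (GRF10).

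Photosynthesis genes were lower in both the light-harvesting and the carbon-fixing part. The 12 light-harvesting and nuclear photosystem genes had a median log2 change of -1.67, all negative, with 2 past the threshold, cab-m1 and lhcb4 (camera adjusted p = 4.9e-06; adjusted p = 0.605 with an estimated correlation). Under quantile normalization the median was -0.99. lhcb4 fell from 33.2 ± 8.83 to 9.07 ± 1.82 FPKM. Of 11 carbon fixation and C4 cycle genes, 5 fell (median -1.33; camera adjusted p = 5.5e-04; adjusted p = 0.605 with an estimated correlation). Under quantile normalization the median was -0.81. Besides pep1 the 5 included 2 rubisco small subunit genes, at 274 ± 30.7 and 323 ± 87.1 FPKM in HN and 49.7 ± 2.87 and 57.0 ± 10.2 in LN. The gene of rubisco activase, rca1, fell from 11.6 ± 1.97 to 2.24 ± 0.714 FPKM. Another 10 loci carry names of plastid genes, but all 10 lie on nuclear chromosomes in the table's coordinates. Their median was -0.63 with 0 past limma's threshold, 4 lower at an unadjusted p under 0.05 and 5 lower in the authors' deposited table (camera adjusted p = 0.0181; adjusted p = 0.644 with an estimated correlation). This call ended with a filter at 5 FPKM and without LN1, and the median ranged from -0.95 to -0.23 over the alternatives. Of these loci, ATPB had a log2 change of -1.06 and NDHK one of -0.13.

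Benzoxazinoid synthesis, the pathway of the main defence metabolites of young maize, was lower. The median over 9 genes was -1.61 and 5 fell (camera adjusted p = 5.1e-05; adjusted p = 0.605 with an estimated correlation). BX4 fell from 292 ± 51.1 to 63.5 ± 7.83 FPKM, CYP71C3 (BX5) from 601 ± 151 to 120 ± 16.1, CYP71C2 (BX3) from 289 ± 46.6 to 80.8 ± 14.4 and BX14 from 5.02 ± 1.91 to 0.596 ± 0.0843. CYP71C4 was not on this list.

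Nitrogen assimilation genes were lower by a smaller median, -0.53 over 12 genes (camera adjusted p = 0.0139; adjusted p = 0.605 with an estimated correlation). The call ended under a filter at 5 FPKM, under quantile normalization and without HN1. Only GLN2, a glutamine synthetase gene (chromosome 10, 145900759 to 145906241), passed the threshold, at 106 ± 0.329 FPKM in HN and 32.1 ± 2.48 in LN (log2 change -1.70, SE 0.20, limma adjusted p = 0.0431). Of the 12, 10 were negative and 2 positive. The 2 positive ones, outside the naming rule, were the glutamine synthetase genes Gln1-4 and gln1-3, the most abundant of the list (means of 636 and 104.9 FPKM). They had log2 changes of 0.85 and 0.38 and did not pass (limma adjusted p = 0.244 and 0.340). At an unadjusted p under 0.05, 5 were lower and 0 higher, and 4 were lower adjusted over the list alone. The authors' deposited table called 4 lower and 0 higher. Also outside the naming rule, NNR1 and NIR had log2 changes of -2.09 and -1.515 (limma adjusted p = 0.0534 and 0.0566). NRT1.2, the 1 tested nitrate transporter gene, was at 4.90 ± 0.599 and 4.82 ± 0.874 FPKM.

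**Figure D2:**
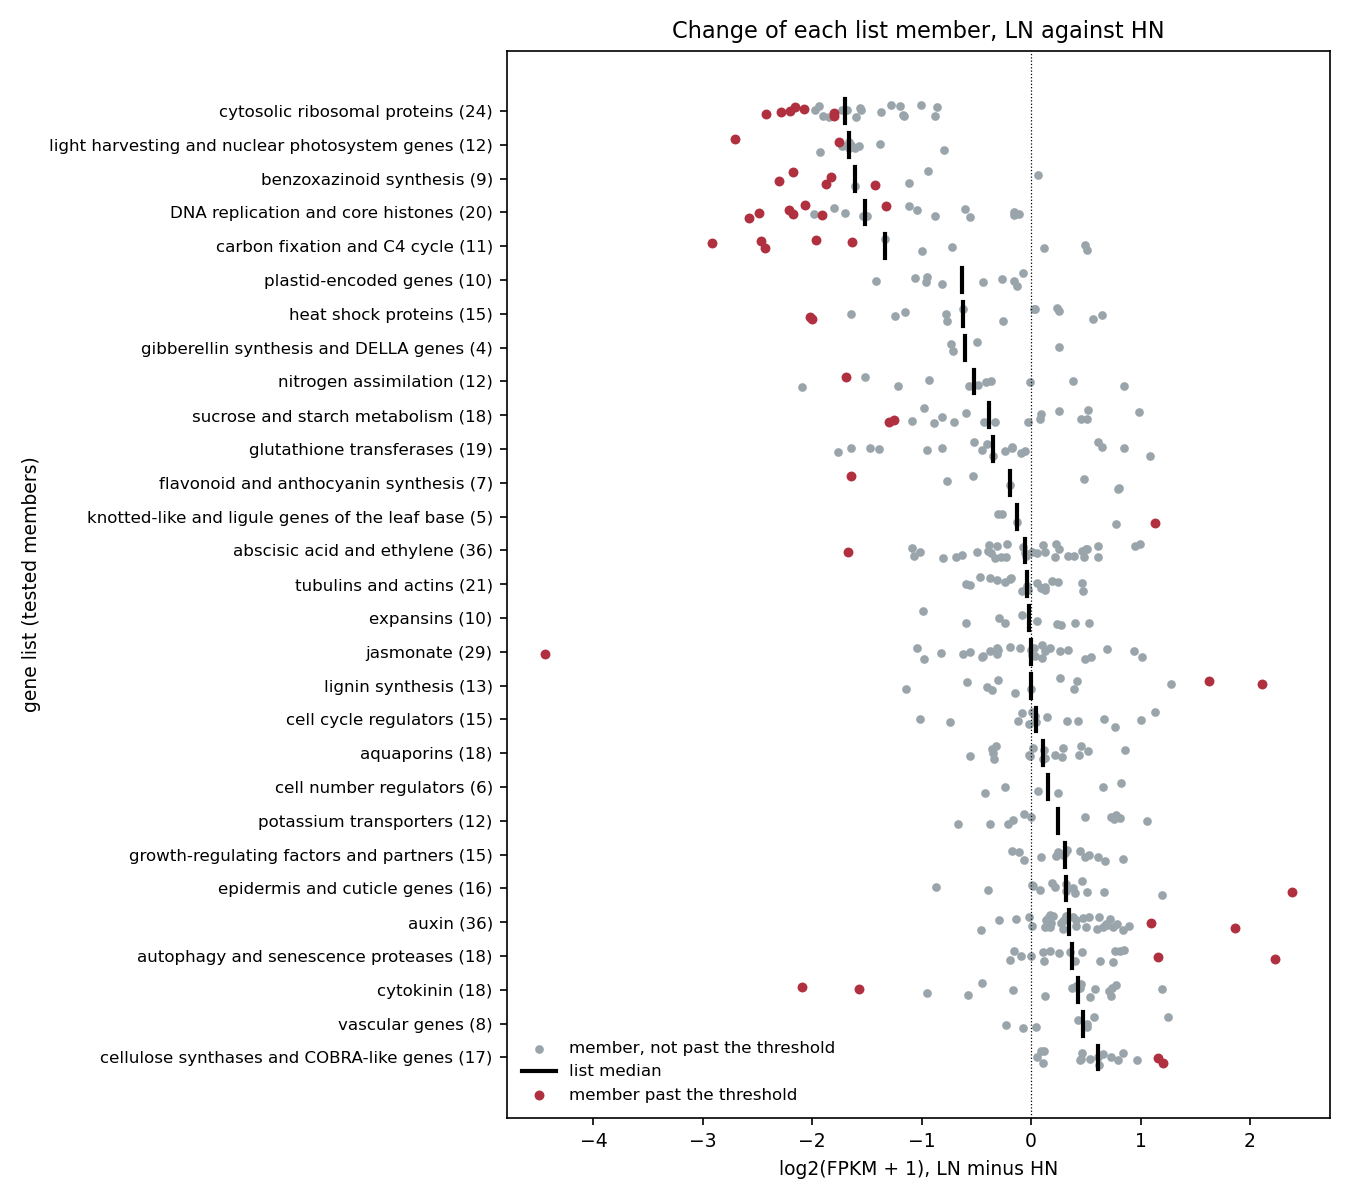
Change in log2(FPKM + 1), LN minus HN, for each tested member of the symbol lists with at least 3 tested members, with a bar at each list's median and members past the threshold in red. The ribosomal protein list has the lowest median (-1.71) and the cellulose synthase and COBRA-like list the highest (0.61).

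Genes of cellulose deposition were higher. All 17 tested cellulose synthase, related synthase and COBRA-like genes had positive changes, with a median of 0.61 (camera adjusted p = 8.5e-04; adjusted p = 0.605 with an estimated correlation). Of these, 2 passed limma's threshold, 8 were higher at an unadjusted p under 0.05 and 4 were higher in the authors' deposited table. The log2 changes ran from 0.05 for bk4 to 1.20 for CesA12. CesA12 rose from 5.92 ± 0.824 to 14.9 ± 0.529 FPKM, and the COBRA-like gene bk2, whose loss makes stalks brittle, from 10.96 ± 1.42 to 25.7 ± 0.996. The narrower cellulose list fixed before the data were examined had 12 tested members, all positive, with 1 past the threshold and 2 higher adjusted over the list alone (median 0.61, and 0.95 under quantile normalization; camera adjusted p = 0.0031; adjusted p = 0.58 with an estimated correlation). The lignin list fixed then held 4 tested members, all laccase loci (1 named Laccase-17 and 3 named Laccase-13) and all positive, with 2 past the threshold and 3 higher adjusted over the list alone (median 1.46, camera adjusted p = 0.0052; adjusted p = 0.58 with an estimated correlation). Those 2 were Laccase-17 and 1 Laccase-13 locus (chromosome 3, 183701020 to 183703536), the latter rising from 0.423 ± 0.0279 to 5.24 ± 1.43 FPKM. The wider lignin list of 13 genes had a median of 0.0032 and a camera adjusted p of 0.586.

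Wall-loosening and turgor genes did not pass the threshold. Of 10 expansin genes, 0 passed limma's threshold, 1 was higher and 1 lower at an unadjusted p under 0.05, and 1 was lower in the authors' deposited table. The abundant expB8 was at 176 ± 17.7 FPKM in HN and 144 ± 11.8 in LN, and expB2 at 152 ± 32.5 and 98.9 ± 1.30. The 1 tested xyloglucan endotransglucosylase gene, xth1, had a log2 change of 0.27. The 18 aquaporin genes and the 21 tubulin and actin genes also had 0 past limma's threshold, 0 at an unadjusted p under 0.05 and 0 in the authors' deposited table. The water channel genes PIP1-1 and PIP1-2 were at 1701 ± 777 and 1171 ± 471 FPKM in HN and at 1981 ± 264 and 1306 ± 67.1 in LN. The tubulin genes TUBA2 and TUBA4 were at 2162 ± 469 and 1714 ± 501 FPKM in HN and at 2020 ± 70.5 and 1838 ± 85.2 in LN. Camera's adjusted p was 0.825 for expansins, 0.963 for aquaporins and 0.673 for tubulins and actins.

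Hormone genes moved unevenly. In the auxin list 32 of 36 genes were positive, with a median of 0.35 (camera adjusted p = 0.0011; adjusted p = 0.605 with an estimated correlation). AUX1 (chromosome 6, 80078085 to 80079839) and AUX17 rose from 1.248 ± 0.399 to 7.12 ± 0.0623 and from 10.7 ± 0.271 to 24.1 ± 0.0760 FPKM. The cytokinin response regulator genes RR7 and RR6 fell from 18.99 ± 4.25 to 3.63 ± 0.394 and from 3.72 ± 0.660 to 0.578 ± 0.117 FPKM, while the 18 genes of that list had a median of 0.43 (camera adjusted p = 0.541). Of 36 abscisic acid and ethylene genes, acco20, an aminocyclopropane carboxylate oxidase gene, fell, from 3.04 ± 0.711 to 0.255 ± 0.0443 FPKM. Of 29 jasmonate genes lox1 fell. Camera's adjusted p was 0.673 and 0.38 for these lists.

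Autophagy and senescence protease genes were higher, with a median of 0.38 over 18 genes (camera adjusted p = 0.0139; adjusted p = 0.605 with an estimated correlation; the call ended without LN2). Under quantile normalization the median was 0.60. The 2 past the threshold were the senescence-linked legumain genes see2b and see2a, the latter rising from 11.2 ± 1.04 to 26.4 ± 0.188 FPKM. The 12 ATG genes of the list had a median of 0.43 with 0 past the threshold. The other members, CCP1, ccp2, mir3 and mir2, had log2 changes of 0.0031, 0.11, 0.12 and -0.20.

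Among the remaining lists, camera called none in the main setting, and some were called under an alternative. The heat shock list held 15 genes, of which a pair of neighbouring chaperonin 60 loci fell, with log2 changes of -2.025 and -1.999 (list median -0.62, with -1.18 without HN1 and -0.069 without HN2; camera adjusted p = 0.128). Of 18 sucrose and starch genes, Agp2 (chromosome 2, 174023582 to 174034507) and SPP2 fell, from 10.7 ± 1.13 to 3.89 ± 0.105 and from 3.01 ± 0.162 to 0.641 ± 0.286 FPKM (camera adjusted p = 0.153). Of 2 loci named pac1, a regulator of anthocyanin synthesis, 1 (chromosome 5, 196666687 to 196670652) fell from 63.5 ± 18.8 to 19.3 ± 3.89 FPKM, while the other had a log2 change of -0.19 (limma adjusted p = 0.616). The flavonoid list held 7 genes (camera adjusted p = 0.825). KNOX1, a homeobox gene of the class marking the leaf base, rose from 8.49 ± 1.10 to 19.8 ± 1.67 FPKM among 5 genes (camera adjusted p = 0.673). CER1 was the 1 call among 16 epidermis and cuticle genes (camera adjusted p = 0.109). The 12 potassium transporter, 19 glutathione transferase and 8 vascular genes had 0 past limma's threshold. At an unadjusted p under 0.05, 5, 3 and 3 were higher and 1, 5 and 0 lower. The authors' deposited table called 1 of each list higher and 1, 6 and 0 lower. The medians were 0.25, -0.35 and 0.47 (camera adjusted p = 0.354, 0.153 and 0.153). The glutathione transferase median was -0.64 without HN1, where camera called the list, and 0.11 without HN2. The most abundant of each had log2 changes of -0.06 (HAK8), -0.21 (HAK23), -0.40 (GST1), -1.65 (GST3, limma adjusted p = 0.0739), 0.04 (SCR) and 0.43 (sut4). The phosphate transport and seed storage lists had 2 and 1 tested members, too few for camera. pho1, pht7 and gz27 had log2 changes of 0.41, -0.48 and -0.11. Of the planned lists not yet given, heat shock proteins, auxin and jasmonate held 14, 4 and 12 tested members, with camera adjusted p of 0.149, 0.453 and 0.77. Yucca6, IAA12, TIFY30 and TIFY27 had log2 changes of 0.17, 0.53, -0.0044 and -0.62. The single planned-list members csh9 and glossy2 had changes of 0.33 and -0.39, and the flavonoid genes bronze and c2 of -0.77 and -0.53.

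The HN libraries differed from each other more than the LN libraries did. The SD of the difference in log2(FPKM + 1) was 0.69 between HN1 and HN2 and 0.41 between LN1 and LN2. In HN2 relative to HN1, loci of 500 to 1000 bp had a median difference of 0.51 and loci over 10000 bp of -0.27, while LN2 minus LN1 gave 0.06 and -0.0019. The mean of LN minus HN1 gave 0.10 and 0.12 over those bins, without such a trend. LN minus HN with both HN libraries, the comparison used for the results, did carry it, with -0.13 and 0.23. The median locus span was 2762 bp for the ribosomal protein list, 2882 bp for replication and histones and 1614 bp for light harvesting, against 4231 bp for annotated single-gene loci outside the lists. The cellulose synthase and COBRA-like list, which was higher, had a median span of 5779 bp and a median change of 0.71 against HN1 alone. Against HN1 alone the ribosomal protein list had a median of -1.32, replication and histones -1.17, light harvesting -1.32, benzoxazinoids -1.35 and carbon fixation -1.25.

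**Figure D3:**
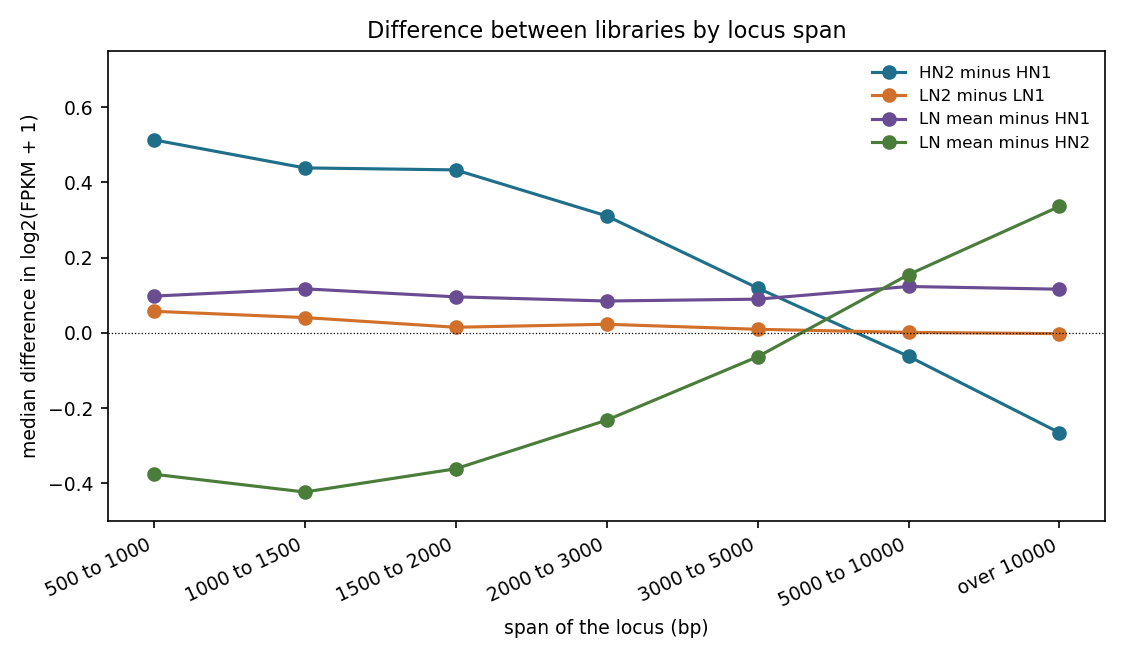
Median difference in log2(FPKM + 1) between libraries, by the span of the locus in bp, for annotated single-gene loci outside the lists. HN2 minus HN1 runs from 0.51 in loci of 500 to 1000 bp to -0.27 in loci over 10000 bp, and LN minus HN1 stays between 0.08 and 0.12.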

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

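The alternatives other than the pseudocount of 0.1, the filters, the stricter thresholds, the left-out libraries, the estimated correlation and fry were chosen after seeing the data. No paired analysis was possible because both HN columns carry the same name and so no replicate number. Alternatives that need counts (other size factors, count filters, DESeq2 and edgeR's exact test) were not run because the values are FPKM. limma called 4.985% of the tested loci (266 higher, 855 lower). This became 0.449% (32 and 69) with a pseudocount of 0.1, 0.00329% (1 and 0) with the filter at any value above 0, where 8174 loci had an unadjusted p under 0.05, and 0.00445% (1 and 0) at an adjusted p under 0.01. It was 12.1% (971 and 1749) under quantile normalization, 7.91% (479 and 1288) without loci listed at 0 in one library, 10.3% (562 and 1474) over annotated single-gene loci, 10.3% (565 and 1752) with the trend on locus span removed and 19.4% (1295 and 3064) by the authors' q-values. Leaving out 1 library gave 0.338% to 46.6%, with 22 to 5165 higher and 43 to 5305 lower, the lone library of a group being assumed to vary like the other group. At 5 FPKM the calls were 8.74% of fewer tested loci (276 and 1087). For this and the other alternatives the number of calls stayed within 1.5 times that of the main setting. With 1 library left out, the spread came from 1 pair alone, the closer LN pair or the wider HN pair. The cause of the other moves was not tested. The median change of all tested loci was 0.07, and 0.16 with median-of-ratios scaling.

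Camera called 2 of 5 planned lists and 10 of 29 symbol lists. With an estimated correlation the numbers were 0 and 0, and with fry 0 and 3. Of these 3, only carbon fixation was also called by camera, and cell number regulators and sucrose and starch were not. The correlations estimated for carbon fixation (-0.081), auxin (0.0059) and nitrogen assimilation (-0.031) lay below the preset 0.01. Their unadjusted camera p still rose, from 9.5e-05 to 0.0548, from 2.6e-04 to 0.0609 and from 0.0041 to 0.094. For these lists a higher correlation was therefore not why the call was lost. Under the camera alternatives at the preset correlation both planned lists and 7 of the 10 symbol lists were called each time they were tested, with nitrogen assimilation, the plastid-named loci and the proteases as the exceptions. The planned lignin list had too few members to be tested at 5 FPKM. Quantile normalization brought the medians of ribosomal proteins, light harvesting and carbon fixation to -1.02, -0.99 and -0.81, and those of proteases and planned cellulose to 0.60 and 0.95. Leaving out 1 library moved the median by over 1.5 times in 1 of the 10 called symbol lists, the plastid-named loci (-0.70 to -0.42). It did so in 13 of the symbol lists not called and in 2 of the planned lists not called. Of the lists not called in the main setting, 1 planned and 5 symbol lists were called under some alternative. Planned heat shock was called at 5 FPKM and without HN1 or LN1, and the heat shock symbol list without HN1 or LN1. Epidermis and cuticle was called under quantile normalization and without HN2 or LN2, tubulins and actins under quantile normalization, glutathione transferases without HN1, and sucrose and starch without HN2. Of the 48 named genes past the threshold, 0 changed direction under any alternative. The number still called was 12 with a pseudocount of 0.1, 0 with the filter at any value above 0, 0 at an adjusted p under 0.01, 6 without LN1, 6 without LN2 and at least 43 under each other alternative. Of the 37 named genes that did not pass, 15 were called without HN1, 3 without HN2, 5 under quantile normalization, 1 with the span trend removed and 4 by the authors' q-values.

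Changes of sign were seen in lists and genes that did not pass the threshold, and their cause was not tested. With the filter at any value above 0 the planned jasmonate list had a median of -0.0099. At 5 FPKM it was -0.0044, and that of the 13 lignin genes was -0.31. With the span trend removed, planned jasmonate was at -0.081, expansins at 0.10, CNR6 at -0.14 and NRT1.2 at 0.067. Median-of-ratios scaling put abscisic acid and ethylene at 0.043, expansins at 0.079, jasmonate at 0.094, tubulins and actins at 0.050, TUBA2 at 0.018, cycD2 at 0.014, NRT1.2 at 0.059, HAK8 at 0.036 and TIFY30 at 0.094. Quantile normalization put abscisic acid and ethylene at 0.023, expansins at 0.23, tubulins and actins at 0.53, expB8 at 0.38, TUBA2 at 0.25, cycD2 at 0.18, CNR8 at 0.13, HAK8 at 0.21, GST1 at 0.37, TIFY30 at 0.42 and glossy2 at 0.37. The authors' deposited table put CNR6 at -0.043 and SCR at -0.10.

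With 1 library left out, list medians ranged from -0.29 to 0.15 for planned jasmonate, -1.09 to 0.010 for planned heat shock proteins, -0.26 to 0.56 for aquaporins, -0.063 to 0.24 for cell cycle regulators, -0.19 to 0.37 for lignin synthesis, -0.045 to 0.018 for abscisic acid and ethylene, -0.18 to 0.12 for expansins, -0.43 to 0.048 for flavonoids, -0.64 to 0.11 for glutathione transferases, -0.28 to 0.041 for jasmonate, -0.27 to 0.034 for knotted-like genes and -0.24 to 0.18 for tubulins and actins. Gene changes ranged from -0.17 to 0.68 for Dwarf1, -0.99 to 0.011 for D8, -0.19 to 0.77 for PIP1-1, -0.20 to 0.64 for PIP1-2, -0.30 to 0.14 for TUBA2, -0.17 to 0.43 for TUBA4, -0.30 to 0.13 for cycD2, -0.86 to 0.017 for CNR8, -0.023 to 0.15 for CNR6, -0.50 to 0.15 for GRF4, -0.18 to 0.13 for NRT1.2, -0.39 to 0.14 for NDHK, -0.11 to 0.94 for pho1, -0.999 to 0.048 for pht7, -0.14 to 0.013 for HAK8, -0.37 to 0.46 for SCR, -0.29 to 0.060 for gz27, -0.28 to 0.94 for csh9 and -0.27 to 0.26 for TIFY30.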

Other observations

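Every test in this part was chosen after the data had been seen, and of the tests of explanations only that with matched random lists was written before its result. Grouping tested genes by the letters their symbols share gave 91 families of at least 5 genes. Of these, 6 had a median log2 change in the lowest 0.5% of 10000 random lists matched on mean level and locus span, and 3 in the highest 0.5%, where 0.91 families would lie in the tails together if genes were independent. The random lists hold unrelated genes, while genes of a list were often correlated (0.75 for ribosomal proteins and 0.66 for aquaporins as estimated by camera), so more families than that would lie there by chance. Families also share genes under different names, so some genes are counted more than once. Among the 6, ARPP and RPP overlap, as arpp2a-2 is also named rpp2a-2. The NF-YA family stood highest, with a median of 1.68 over 6 genes, all positive, above every one of the 10000 matched lists. limma called 3 of them, NF-YA11, NF-YA13 and 1 of 2 loci named NF-YA4, which rose by 1.48 (limma adjusted p = 0.0471). NF-YA7 was at 7.48 and 2.96 FPKM in the HN libraries and 17.7 and 18.4 in the LN libraries (limma adjusted p = 0.0614), and NF-YA14 had an adjusted p of 0.112. The other NF-YA4 locus had a log2 change of 1.65 (limma adjusted p = 0.0989). The authors' deposited table gave NF-YA7 a log2 fold change of 1.64 with q = 0.00382, that NF-YA4 locus q = 0.0332 and NF-YA14 q = 0.0603. The families PPR (5 genes, median -1.12, percentile 0.32) and PIP (8 genes, median 0.17, percentile 99.6) were the others among the 9 that did not repeat a list called by camera. limma called 0 PIP genes, and the direction is open, since the aquaporin list, with a camera adjusted p of 0.963, had medians from -0.26 to 0.56 with 1 library left out.

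The drop of the ribosomal protein, replication and light-harvesting lists in LN is a pattern for which technical explanations were weighed. After the trend on locus span was removed from each library, the 3 medians were still at or below -1.42, which argues against the locus-span trend of HN2 as the whole cause. Camera's adjusted p at the preset correlation was then at most 9.4e-06. The removal left the ribosomal protein median at -1.71, though without it that median was -1.32 against HN1 and -2.03 against HN2. So the removal did not reach the difference between the HN libraries in that list. A trend on transcript length, which locus span only approximates, was not tested for these lists. Before the removal, camera with an estimated correlation gave each of the 3 lists an adjusted p of 0.605. The 3 medians lay at or below the 0.19th percentile of random lists matched on level and span, which argues against a trend common to abundant genes in short loci as the whole cause. The random lists themselves had medians of -0.73 for ribosomal proteins, -0.04 for replication and -0.63 for light harvesting, so part of the ribosomal protein and light-harvesting drops was shared with other loci of that level and span. As these lists hold unrelated genes, the percentiles set aside only the shared trend, not a chance shift of genes that vary together. A single shift of the harvested piece along the leaf would be expected to move genes of dividing cells and of greening tissue in opposite directions. Both medians were at or below -1.52, with upper quartiles of -0.81 and -1.60. These values are the pattern itself, so they are no separate test of a shift. Other markers were mixed. The leaf-base gene KNOX1 rose while its list of 5 genes had a median of -0.13, and the 15 cell cycle regulators had a median of 0.05. The nitrogen supply itself stays open as a hypothesis, as does a shift of the piece, alone or combined with another change.

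The HN pair differed more than the LN pair, and a trend on locus span in HN2 was weighed as a technical explanation. Short loci (500 to 1500 bp) minus long loci (over 10000 bp), all at 5 FPKM or more and outside the lists, gave 0.82 for HN2 minus HN1 and -0.0049 for LN minus HN1. After the span trend was removed from each library, the median absolute difference at 20 FPKM and more was still 2.92 times as large in the HN pair as in the LN pair (0.39 against 0.13), which argues against that trend as the whole cause. The lower depth of HN2 was weighed at 20 FPKM and more. There the median absolute difference before that removal was 3.43 times as large in the HN pair (0.46 against 0.13, 6305 loci). Estimated depth differed less, at 64.4% of LN1 in HN2, 75.8% in HN1 and 91.6% in LN2, which argues against depth as the whole cause. Counting noise at that level was not measured, because absolute depth is unknown. A trend on transcript length, which locus span only approximates, was not tested and stays open, as do differences between the plants of the HN libraries, which the labels do not describe.

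In 19 loci, 1 library was listed at 0 while each other library had at least 20 FPKM, and 11 of these loci spanned at most 250 bp. Both LN libraries lay on the same side of both HN libraries in 14937 of the tested loci, 66.4%, against 33.3% on average by chance. Loci vary together, so with 4 libraries the share without any effect can lie far from that average. Nothing is concluded from the difference. Among the 1125 loci in the top 5% by mean FPKM, limma called 152 lower and 5 higher.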
